A study of Homo sapiens with 18 samples.

How the data were processed

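Polyadenylated RNA of HCT116 cells was sequenced with a directional kit as single reads of 100 nt. The design had 3 siRNA pools (siControl, siIGF2BP2, siIGF2BP3; 75 nM, 48 h) crossed with DMSO or 5 µg/mL TM for 4 h, in 3 libraries per group, 18 in all. The deposited table holds counts per gene, which the authors made with STAR 2.7.5c and featureCounts 2.0.1 on hg38, as their processing notes name them. The notes do not give the strand setting, the annotation release or how reads that map to several places were counted. Values of near-identical genes, such as HSPA1A and HSPA1B, RAB6A and RAB6C, or KRTAP2-3 and KRTAP2-4, depend on the latter. The row numbers of the table skip, so it is part of a longer one, and totals per library are totals of this part. They ran from 16888957 to 30788371. The table has 19962 genes, 3596 of them at 0 in all libraries. A symbol was found for 19362, and 19847 have a transcript in GENCODE 29, the release used for symbols, positions, GC content and length.

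Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr on the 6 groups, which left 12484. Libraries were scaled by TMM, a quasi-likelihood model with 1 mean per group was fitted to all 18 libraries, and each contrast was tested by glmQLFTest with Benjamini-Hochberg adjustment over the genes tested, at 0.05. A gene past that is called. The 11 contrasts were TM against DMSO within each siRNA pool, each target pool against siControl within each treatment, siIGF2BP3 against siIGF2BP2 within each treatment, and the interaction of each target pool with TM. SE is the log2 fold change divided by the square root of F. CPM are TMM-scaled, and principal components used log2 CPM with a prior count of 2.

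The 25 gene lists were written before the data were examined, as were the comparisons, the rule for named genes and the alternatives not said to be added. They cover PERK-ATF4, ATF6 and IRE1-XBP1 targets, RIDD substrates, ERAD machinery, N-glycosylation, cytosolic heat shock, cholesterol biosynthesis, G1-S and G2-M genes, p53 targets, interferon-stimulated genes, reported IGF2BP-bound mRNAs, cytosolic ribosomal proteins, nuclear-encoded OXPHOS, mitochondrially encoded mRNAs, m6A machinery, mRNA decay factors, immediate early genes, apoptosis regulators, glycolysis, autophagy genes, epithelial and mesenchymal markers and markers of other cell types. They were written from general knowledge, and 1 member, H19, is not in the table. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 25 lists, with camera at an estimated correlation, and with fry, which asks whether members move one way and compares them with no other genes.

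Genes were named by rule. They had to pass the threshold, have a symbol and a mean of at least 5 CPM, and, except in interactions, have groups that do not overlap. The 8 with the largest change each way were named, or 5 in the interactions, the direct contrasts and the TM response of the siRNA groups. IGF2BP1, IGF2BP2 and IGF2BP3 were named in each siRNA comparison. For each list described, up to 4 called members with the largest change were eligible, and some were followed into other comparisons.

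The alternatives were RLE scaling, DESeq2 1.42.0, no low-count filter, a stricter filter (5 CPM in 3 libraries), a fit of the groups compared alone, a term for replicate number, and leaving out each library in turn. The replicate numbers are not described as pairs. Deviations from group means correlated between libraries of the same number by -0.025 to 0.054 over 15 group pairs (mean 0.019, against -0.01 for other numbers). These correlations are weak, but 15 of 18 libraries lay closest to their own number, so a structure shared by replicate number is not excluded. The term was kept as an alternative and not in the model. Removal of a GC content and length trend from each library was added after seeing the data. It used a spline over the tested genes with both values known. List tests without siControl TM replicate 3 were also added then. The share of a library's deviation that followed GC content and length was measured on the 9539 genes above 3 log2 CPM. Spread for values with no test is the jackknife SE over libraries; the SD of leave-one-out values was used at first and replaced once its output was seen.

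Agreement between both siRNA effects was set against 20 simulations in which unchanged groups were compared with the same siControl libraries. Slopes of the TM response were orthogonal, over called genes. Group labels were also exchanged in all 10 splits of 6 libraries, or in 100 drawn splits for the interactions, with the additive effects of siRNA and treatment put into the offsets of each gene. The model was tested on simulated data with 50 genes changed per fold. It recovered 94% of genes changed 1.5-fold and 100% of those changed 2-fold in siIGF2BP3 against siControl in DMSO, and 78% and 96% in the siIGF2BP3 interaction. Of genes changed 1.25-fold it recovered 80% in that comparison and 48% in the interaction. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for sequence searches and figures. No sample was left out, and no column of the table was unassigned.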

Results

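The series measured polyadenylated RNA by sequencing in HCT116 cells, an established human colorectal carcinoma line. Cells were transfected for 48 h with 75 nM of an siRNA pool against IGF2BP2, against IGF2BP3 or with a nontargeting pool (siIGF2BP2, siIGF2BP3 and siControl). Both targets encode RNA-binding proteins of the insulin-like growth factor 2 mRNA-binding family. The cells then received DMSO, the solvent, or 5 µg/mL tunicamycin (TM) for 4 h. TM blocks N-linked glycosylation, so that unfolded glycoproteins build up in the endoplasmic reticulum (ER) and start the unfolded protein response. The 18 libraries fell into 6 groups of 3, one per pool and treatment. They held 16888957 to 30788371 counts over the 19962 genes in the table, of which 12484 passed the low-count filter and were tested. The first principal component, with 49.3% of the variance, parted the TM from the DMSO libraries. The second, with 14.7%, parted the siIGF2BP2 libraries from the others. In siControl TM, replicate 3 lay apart from replicates 1 and 2, and 57.4% of the variance of its deviation followed GC content and transcript length.

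The first question was whether each pool lowered its target. IGF2BP2 (ENSG00000073792, hg38 chromosome 3, 185643739 to 185825056, minus strand) stood at 195 ± 4 CPM, counts scaled to the library total (SD, n = 3), in siControl DMSO and at 36.5 ± 3.1 in siIGF2BP2 DMSO, 18.8% of the control level. Under TM it stood at 226 ± 5.9 in siControl and at 34.7 ± 3.5 in siIGF2BP2, which is 15.4%. The log2 fold changes were -2.41 ± 0.05 (SE, adjusted p = 8.77e-32) and -2.69 ± 0.05 (adjusted p = 6.6e-34). IGF2BP3 (ENSG00000136231, chromosome 7, 23310209 to 23470467, minus strand) stood at 115 ± 3.9 CPM in siControl DMSO and at 26.7 ± 0.23 in siIGF2BP3 DMSO, 23.1% of the control level. Under TM its levels were 95.7 ± 8.2 and 18.5 ± 0.72, which is 19.3%. The log2 fold changes were -2.11 ± 0.06 (adjusted p = 7.38e-29) and -2.36 ± 0.06 (adjusted p = 9.22e-30).

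Each pool was also read out on the other family members. The siIGF2BP3 pool left IGF2BP2 at 96.4% of control in DMSO (adjusted p = 0.556) and 95.7% in TM (adjusted p = 0.394). The siIGF2BP2 pool lowered IGF2BP3 to 77.2% of control in DMSO (log2 fold change -0.37 ± 0.05, adjusted p = 1.96e-07). In TM the same pool left it at 93.6% (-0.09 ± 0.05, adjusted p = 0.151). Without siControl TM replicate 3 the latter passed the threshold at -0.17 with adjusted p = 0.00254, and the adjusted p ranged from 0.000419 to 0.645 over the alternatives. The difference between these 2 effects was 0.28 ± 0.07 (adjusted p = 0.0565). It passed the threshold without siControl DMSO replicate 1 (adjusted p = 0.045), siControl TM replicate 1 (0.00321) or siIGF2BP2 TM replicate 3 (0.0432). With all libraries it passed by DESeq2 (0.0385), with no filter (0.0194), with the stricter filter (0.0336), with the GC and length trend removed (0.0234) and with a term for replicate number, in a range of 0.00321 to 0.157 over the alternatives. The effect of the siIGF2BP2 pool on IGF2BP2 itself differed between treatments by -0.28 ± 0.08 and did not pass (adjusted p = 0.102). It passed without siControl TM replicate 3 (0.03) or siIGF2BP2 TM replicate 2 (0.0287), by DESeq2 (0.0385), with no filter (0.0197), with the GC and length trend removed (0.042) and with a term for replicate number, in a range of 0.0197 to 0.466. The effect of the siIGF2BP3 pool on IGF2BP3 differed by -0.25 ± 0.08 (adjusted p = 0.306), and passed with the trend removed (0.0281, in a range of 0.0281 to 0.684). IGF2BP1 (ENSG00000159217, chromosome 17) stayed under 1 CPM in every group, at 0.333 ± 0.2 to 0.533 ± 0.32, and passed in none of the siRNA comparisons.

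**Figure D1:**
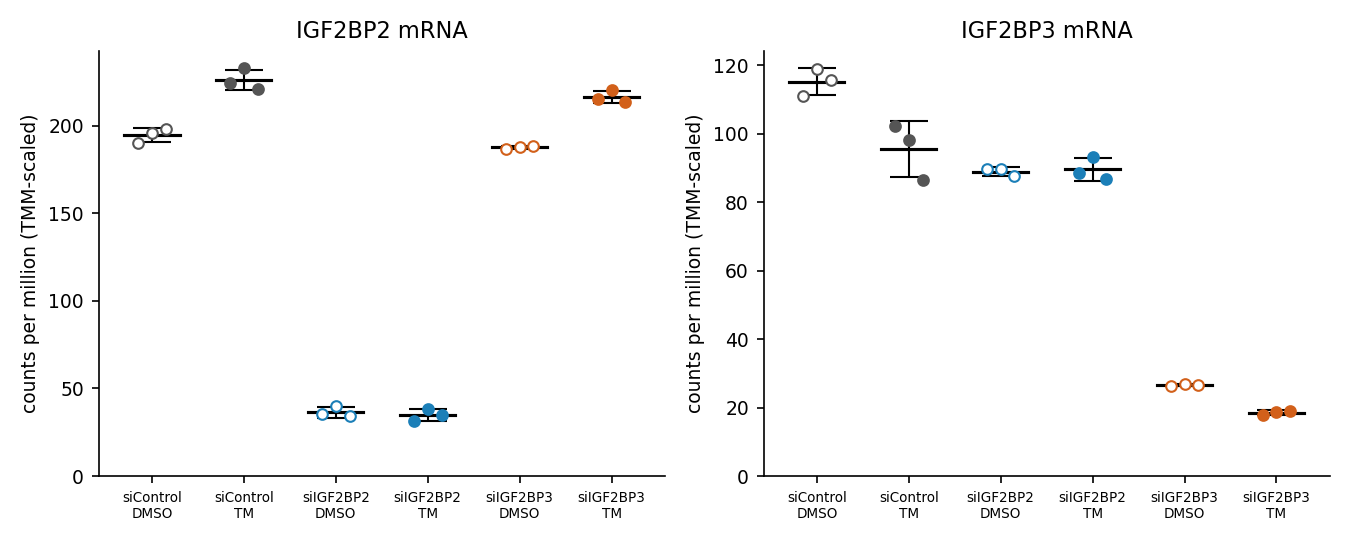
TMM-scaled CPM of IGF2BP2 (left) and IGF2BP3 (right) in each library, with the mean (horizontal line) and SD (whiskers) of the 3 libraries per group; open circles are DMSO, filled circles TM. IGF2BP2 fell to 36.5 and 34.7 in the siIGF2BP2 groups, and IGF2BP3 to 26.7 and 18.5 in the siIGF2BP3 groups.

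The response of control cells to ER stress was read from siControl TM against siControl DMSO. The largest rise was in DDIT3, which encodes the stress transcription factor CHOP, from 9.59 ± 0.574 to 689 ± 46.2 CPM (71.7-fold). CHAC1, a glutathione-degrading enzyme, rose 54.3-fold, HERPUD1, a part of ER-associated degradation, 23.2-fold, and SESN2, a stress-induced sestrin, 17.4-fold. LURAP1L, TSC22D3, ATF3 and FICD, the enzyme that AMPylates the chaperone BiP, rose 28.8-, 15.3-, 12- and 10-fold. The largest falls were in AXIN2, a feedback inhibitor of Wnt signalling (6.22-fold), and in the near-identical inducible HSP70 genes HSPA1B (4.66-fold) and HSPA1A (4.43-fold). HOXA13, HAS3, KCNJ12, LRFN1 and CBX2, a Polycomb subunit, fell by log2 fold changes of -1.52 to -1.68. In all of these genes the 3 TM libraries lay on 1 side of the 3 DMSO libraries, as the rule for naming genes requires. Their adjusted p lay between 6.31e-46 and 6.22e-12.

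Targets of all 3 branches of the unfolded protein response rose. Of 37 tested PERK-ATF4 targets, 36 rose and 0 fell (median log2 fold change 1.27). Of 18 ATF6 targets, 17 rose, among them HSPA5, the ER chaperone BiP (2.75 ± 0.04), SEL1L (2.51 ± 0.05) and HYOU1 (2.29 ± 0.04), with a list median of 1.51. Of 32 IRE1-XBP1 targets, 26 rose and 2 fell. The rise was led by DNAJB9 (3.28 ± 0.06), DNAJC3 (2.62 ± 0.05), EDEM1 (2.08 ± 0.07) and the coat protein gene SEC24D (1.96 ± 0.06). With both target pools, described below, the median of this list was smaller than those of the other branches. The ERAD machinery had 18 of 28 members higher and 2 lower, led after HERPUD1 by the ubiquitin ligase SYVN1 (2.73 ± 0.05). Of 44 N-glycosylation genes, 20 rose and 5 fell; GFPT1, which opens hexosamine synthesis, rose by 1.37 ± 0.05, GMPPB by 1.23 ± 0.06 and the oligosaccharyltransferase subunit MAGT1 by 1.10 ± 0.05. These 5 lists passed the list test with adjusted p of 6.85e-176, 2.17e-133, 3.33e-18, 1.64e-21 and 0.000507. With an estimated correlation all 5 still passed (adjusted p = 3.89e-08, 3.89e-08, 0.00125, 1.63e-06 and 0.00388). Adjusted over the list alone, the counts were 36, 17, 27, 18 and 20 higher and 0, 0, 3, 2 and 5 lower.

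Immediate early genes rose as well, 23 of 29 with 3 lower (median 0.90, adjusted p = 7.16e-26, and adjusted p = 0.000275 with an estimated correlation). EGR1 rose by 2.14 ± 0.04, CCN1 by 1.98 ± 0.07, JUN by 1.79 ± 0.06 and FOS by 1.66 ± 0.11. Cytosolic heat shock genes fell, 11 of 17 with 3 higher (median -0.27, adjusted p = 5.82e-09, and 0.0448 with an estimated correlation). Beside HSPA1A and HSPA1B, the constitutive chaperone HSPA8 fell by 0.88 on the log2 scale and its co-chaperone BAG3 by 0.74. Adjusted over the list alone, these 2 lists gave the same counts.

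In 5 further lists the call was lost with an estimated correlation. Of 14 tested substrates of IRE1-dependent decay (RIDD), 8 fell and 2 rose (median -0.33), with TGOLN2 (-1.31 ± 0.05), the complement inhibitor CD59 (-1.29 ± 0.05) and LARGE2 (-0.75 ± 0.05) lower and the clock gene PER1 higher (1.75 ± 0.05). The adjusted p was 0.0023, and 0.148 with an estimated correlation. Of 25 cholesterol biosynthesis genes, 15 rose and 3 fell (median 0.19), led by the sterol carrier STARD4 (1.49 ± 0.06), HSD17B7 (0.90 ± 0.09) and the LDL receptor LDLR (0.80 ± 0.05; adjusted p = 0.00667, and 0.162 with an estimated correlation). Of 26 autophagy genes, 12 rose and 2 fell (median 0.095), among them MAP1LC3B (1.65 ± 0.05) and TFE3 (0.97 ± 0.07; adjusted p = 0.0164, and 0.148 with an estimated correlation). Of 66 nuclear genes of oxidative phosphorylation (OXPHOS), 36 fell and 1 rose (median -0.14), with ATP5MC1 at -0.47 ± 0.05 and NDUFB3 at -0.40 ± 0.06 (adjusted p = 0.00232, and 0.504 with an estimated correlation). Of 13 mitochondrially encoded mRNAs, 11 fell (median -0.20), with MT-ND1 at -0.33 ± 0.03 and MT-ND2 at -0.27 ± 0.03 (adjusted p = 0.00424, and 0.317 with an estimated correlation).

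The other 13 lists did not pass. Median log2 fold changes were -0.11 for G1-S genes (6 higher and 15 lower of 30, adjusted p = 0.0752), -0.038 for G2-M genes (0.449), 0.009 for p53 targets (0.0694), -0.13 for interferon-stimulated genes (0.755) and -0.012 for reported IGF2BP-bound mRNAs (0.236). They were -0.019 for cytosolic ribosomal proteins (0.526), 0.027 for m6A machinery (0.854), 0.087 for mRNA decay factors (0.236), 0.048 for apoptosis regulators (0.526) and 0.10 for glycolysis (0.812). They were -0.023 for epithelial and colonic markers (0.526), 0.45 for mesenchymal markers (0.296) and 0.045 for markers of other cell types (0.968; 4 of 19 markers were expressed enough to test). For the m6A machinery, the epithelial markers and the markers of other cell types, the list test pointed against the sign of the median. Single members of these lists did change. Among apoptosis regulators PMAIP1 (1.23 ± 0.05), the death receptor TNFRSF10B (1.20 ± 0.04) and BBC3 (1.17 ± 0.08) rose while the decoy receptor TNFRSF10D fell (-1.32 ± 0.05). GDF15 rose by 1.96 ± 0.05 and the antiproliferative BTG1 by 2.03 ± 0.07.

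TM against DMSO in siControl called 6067 of 12484 genes by edgeR at an adjusted p of 0.05, 3162 higher and 2905 lower, 250 and 128 of them at least 2-fold. Groups did not overlap in 51.2% of genes, against 10% by chance for 3 against 3 libraries. IGF2BP2 rose with TM by 0.22 ± 0.05 (adjusted p = 0.000114) and IGF2BP3 fell by 0.27 on the log2 scale (adjusted p = 1.31e-05).

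**Figure D2:**
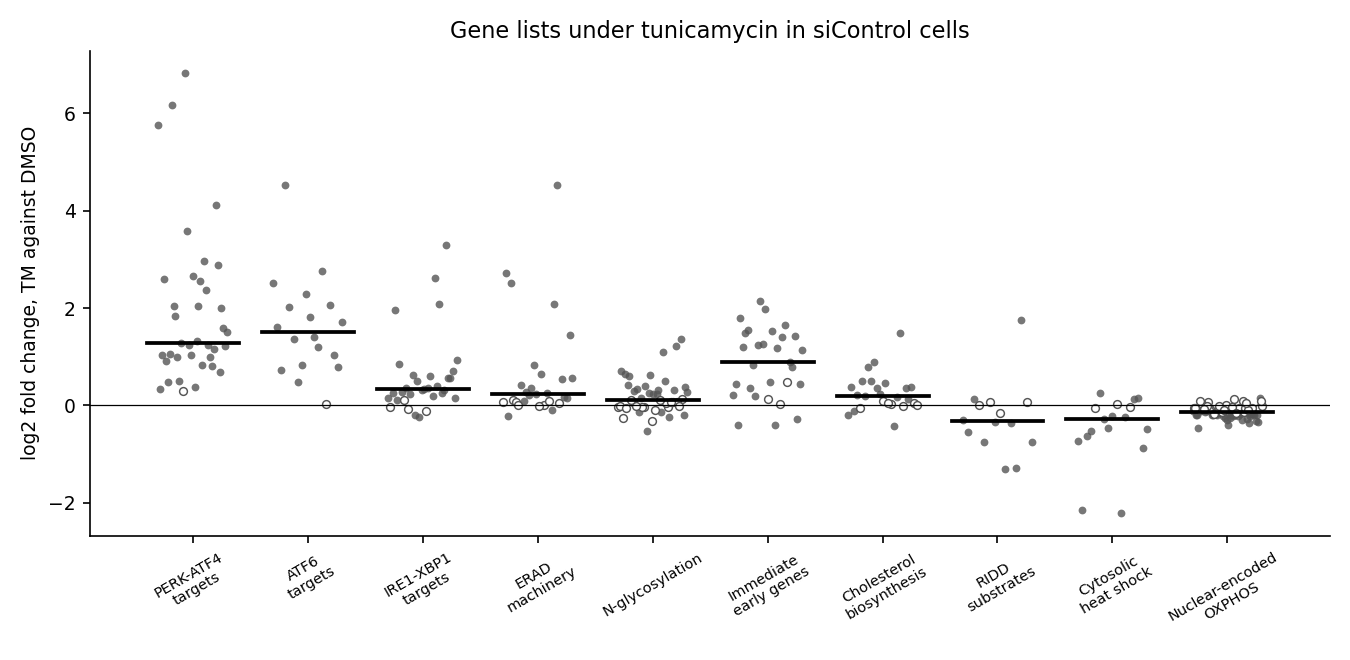
Log2 fold change of each tested member of 10 gene lists, TM against DMSO in siControl cells (3 libraries per group); filled points passed the gene test, open points did not, and horizontal lines are list medians. Medians run from 1.51 for ATF6 targets and 1.27 for PERK-ATF4 targets down to -0.33 for RIDD substrates.

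The effect of IGF2BP3 siRNA without stress was read from siIGF2BP3 against siControl in DMSO. After IGF2BP3 itself, the largest fall was in CA2 (ENSG00000104267, chromosome 8), the cytosolic carbonic anhydrase, from 31.9 ± 1.36 to 8.76 ± 1.08 CPM (3.65-fold). STARD4 fell 2.16-fold, the Golgi GTPase gene RAB6A 2.07-fold, its retrocopy RAB6C, whose shared reads cannot be told from its own here, 2.16-fold, CD59 1.96-fold, FBXL2 1.88-fold and PM20D2 1.78-fold. SCG2, a secretory granule protein, rose 2.22-fold, PSKH1 2.02-fold, the glycine transporter SLC6A9 1.65-fold, the cytoplasmic polyadenylation factor CPEB3 1.6-fold, ZBTB20 1.56-fold and the cytokine signalling inhibitor SOCS1 1.53-fold. These genes had adjusted p from 5.84e-22 to 0.00134 and, by the rule for naming, no overlap between the groups. LURAP1L rose 1.84-fold (adjusted p = 0.0335) and CHAC1 1.57-fold (0.00415), but LURAP1L did not pass without siControl DMSO replicate 1 or 3 or siIGF2BP3 DMSO replicate 1 or 2 (adjusted p = 0.15, 0.19, 0.103 and 0.0847), and CHAC1 did not pass without siControl DMSO replicate 2 (0.0511). Over the alternatives the adjusted p ran from 0.00863 to 0.19 for LURAP1L and from 0.000206 to 0.0511 for CHAC1.

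Cholesterol biosynthesis genes were lower with siIGF2BP3 in DMSO, 16 of 25 with 1 higher (median -0.24), and 20 with 1 higher when adjusted over the list alone. STARD4, HSD17B7 (-0.58 ± 0.11), IDI1 (-0.46 ± 0.06) and the squalene synthase FDFT1 (-0.38 ± 0.04) fell most. The list passed at adjusted p = 6.28e-25, and 0.000416 with an estimated correlation. PERK-ATF4 targets had 11 of 37 higher and 1 lower (median 0.063, adjusted p = 1.01e-06, but 0.124 with an estimated correlation), among them the serine synthesis genes PHGDH (0.43 ± 0.06) and PSAT1 (0.37 ± 0.04). Of 66 OXPHOS genes, 14 fell and 0 rose (median -0.075, adjusted p = 3.39e-08, but 0.524 with an estimated correlation), with UQCRC2 at -0.48 ± 0.04. Of 79 ribosomal protein genes, 5 fell, and 20 adjusted over the list alone (median -0.082, adjusted p = 2.29e-08, but 0.647 with an estimated correlation). IRE1-XBP1 targets (4 of 32 lower), G1-S genes (6 of 30 lower and 2 higher) and glycolysis genes (3 of 23 lower) also passed, with medians of -0.038, -0.027 and -0.045 and adjusted p = 0.524, 0.643 and 0.524 with an estimated correlation. The reported IGF2BP-bound mRNAs did not pass as a list, with 2 of 31 higher and 3 lower (median -0.006, adjusted p = 0.906). The let-7 and IGF2BP target HMGA2 fell by 0.22 on the log2 scale and MYC rose by 0.16 ± 0.04. The m6A machinery (median 0.049, adjusted p = 0.14) and the mRNA decay factors (0.007, adjusted p = 0.515) did not pass either, though of the latter EXOSC10 fell by 0.32 on the log2 scale and ZFP36L1, which destabilises AU-rich mRNAs, rose by 0.30 ± 0.04.

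This comparison called 900 genes, 470 higher and 430 lower, 7 and 10 of them at least 2-fold, and groups did not overlap in 27.2% of genes (10% by chance). The count fell to 589, 532 or 593 without siControl DMSO replicate 1, 2 or 3 and to 548 or 486 without siIGF2BP3 DMSO replicate 1 or 2, and rose to 1387 with the 2 groups fitted alone.

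The same siRNA effect under ER stress was read from siIGF2BP3 against siControl in TM. CA2 fell 5.98-fold, to 3.99 ± 0.45 from 23.7 ± 0.773 CPM, FBXL2 2.56-fold, PM20D2 2.11-fold, the p53 cofactor ZNF385A 2.1-fold, RAB6A 2.06-fold, RAB6C 1.99-fold and the ISG15 protease USP18 1.91-fold. SCG2 rose 2.56-fold, and DIXDC1, CPEB3, EPDR1, NACC2, RFXAP, KLF11 and PSKH1 rose 1.61- to 1.69-fold. These genes had adjusted p from 5.47e-23 to 0.00149 and, by the rule for naming, no overlap between the groups. CD59 fell here too (-0.62 ± 0.06, adjusted p = 2.02e-10).

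Cholesterol biosynthesis genes were lower under TM with siIGF2BP3, 20 of 25 with 0 higher and 21 adjusted over the list alone (median -0.26, adjusted p = 9.44e-23, and 0.000564 with an estimated correlation). STARD4 fell by 0.71 on the log2 scale, MVD by 0.45 and FDFT1 by 0.43. Of 18 ATF6 targets, 8 were lower and 0 higher (median -0.081, adjusted p = 0.000474, but 0.202 with an estimated correlation), with the ER proteins CRELD2 (-0.27 ± 0.04), DNAJB11 (-0.19 ± 0.04) and PDIA4 (-0.17 ± 0.04). Of 23 glycolysis genes, 10 were lower (median -0.093, adjusted p = 7.31e-06, but 0.202 with an estimated correlation), with PFKFB4 (-0.39 ± 0.09), ENO2 (-0.35 ± 0.06) and HK1 (-0.33 ± 0.05). G1-S genes went both ways, 4 higher and 9 lower of 30 (median -0.064, adjusted p = 0.0243, but 0.526 with an estimated correlation), with CCNE2 higher (0.51 ± 0.08) and MCM5 lower (-0.47 ± 0.05). Of 66 OXPHOS genes, 9 fell and 1 rose (median -0.051, adjusted p = 0.00237, but 0.554 with an estimated correlation). Of 79 ribosomal protein genes, 5 fell (median -0.057, adjusted p = 0.00499, but 0.696 with an estimated correlation). Without siControl TM replicate 3, the library whose deviation follows GC content and length, the OXPHOS list no longer passed (median -0.009, adjusted p = 0.229), the ribosomal list stood at 0.006 (0.729), and over the alternatives their adjusted p ran from 0.00106 to 0.554 and to 0.729. Of the mRNA decay factors, ZFP36L1 rose by 0.61 ± 0.04, ZFP36L2 by 0.37 ± 0.04 and AGO2 by 0.33 ± 0.04, while EXOSC10 fell by 0.41 on the log2 scale. As a list they did not pass (10 higher and 4 lower of 55, median 0.005, adjusted p = 0.0956), nor did the reported IGF2BP-bound mRNAs (4 higher and 3 lower of 31, median -0.002, adjusted p = 0.907), of which E2F1 rose by 0.29 ± 0.06 and SRF fell by 0.26 on the log2 scale. PERK-ATF4 targets did not pass here (2 higher and 3 lower of 37, median 0.017, adjusted p = 0.724).

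In TM, siIGF2BP3 called 1573 genes, 723 higher and 850 lower, 3 and 9 of them at least 2-fold, and groups did not overlap in 25.5% of genes (10% by chance). Of 840 lower genes with a searched 3' UTR, 13.2% carried the 7-base sequence TCAGGTA, against 9.5% of all and 10.5% of higher genes. The count of calls was 1005 without siIGF2BP3 TM replicate 3, 1158 without siControl TM replicate 3 and 675 with the 2 groups fitted alone.

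The effect of IGF2BP2 siRNA without stress was read from siIGF2BP2 against siControl in DMSO. INSIG1 (ENSG00000186480, chromosome 7), which holds back sterol synthesis, fell 2.91-fold, from 113 ± 2.28 to 38.7 ± 2.43 CPM. CORO2B fell 3.14-fold, the chromatin protein gene HMGA1 2.18-fold, TNS4 2.04-fold, MFSD2B 1.99-fold, and the splicing factor gene RBM10 and SRPX 1.94-fold each. The hair keratin-associated genes KRTAP2-4 and KRTAP2-3 rose 2.96- and 2.51-fold, FAM81A 2.35-fold, CTXN1 2.22-fold, PSKH1 2.07-fold, SAMD4A 1.97-fold, the CDK4 and CDK6 inhibitor CDKN2C 1.96-fold and REXO5 1.94-fold. These genes had adjusted p from 9.93e-25 to 3.49e-06 and, by the rule for naming, no overlap between the groups.

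ATF6 targets were lower with siIGF2BP2 in DMSO, 11 of 18 with 0 higher (median -0.24, adjusted p = 7.42e-12, and 0.00726 with an estimated correlation). The disulfide isomerase genes PDIA6 (-0.44 ± 0.04) and PDIA3 (-0.35 ± 0.04), HYOU1 (-0.43 ± 0.05) and MANF (-0.39 ± 0.04) fell most. Cholesterol biosynthesis genes were lower, 18 of 25 with 1 higher (median -0.24, adjusted p = 2.81e-14, and 0.00536 with an estimated correlation), with INSIG1, STARD4 (-0.55 ± 0.06), MSMO1 (-0.49 ± 0.07) and IDI1 (-0.39 ± 0.06). Adjusted over the list alone, 12 ATF6 targets and 22 cholesterol genes were lower. Of 17 heat shock genes, 14 were lower (median -0.18, adjusted p = 2.07e-08, but 0.0813 with an estimated correlation), with DNAJB1 (-0.34 ± 0.04) and BAG3 (-0.33 ± 0.05). Of 23 glycolysis genes, 11 fell and 1 rose (median -0.12, adjusted p = 0.000442, but 0.254 with an estimated correlation), with the glucose transporter SLC2A1 at -0.50 ± 0.05 and ALDOC at -0.47 ± 0.09. Of 24 interferon-stimulated genes, 9 rose and 1 fell (median 0.21, adjusted p = 0.00761, but 0.0813 with an estimated correlation), with OAS3 (0.47 ± 0.05) and PARP9 (0.40 ± 0.10). The reported IGF2BP-bound mRNAs went both ways, 8 higher and 6 lower of 31 (median 0.077, adjusted p = 0.67, with the test pointing down), with CDK6 higher (0.55 ± 0.05) and HMGA1 and CCND1 (-0.42 ± 0.03) lower. Outside the lists that passed, ATP5F1D fell by 0.77 on the log2 scale, the decoy receptor TNFRSF10D by 0.57, the mesenchymal marker SERPINE1 by 0.67 and the epithelial keratin KRT18 by 0.36, while BIRC3 rose by 0.72 ± 0.11.

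This comparison called 3353 genes, 1635 higher and 1718 lower, 57 and 13 of them at least 2-fold, and groups did not overlap in 42.7% of genes (10% by chance). Higher genes made up 48.8% of the calls, and 35% with a GC content and length trend removed from each library, an alternative chosen after seeing the data.

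Under ER stress, siIGF2BP2 was compared with siControl in TM. CXCL8, the neutrophil chemokine interleukin-8, rose 3.69-fold, from 5.86 ± 0.927 to 21.4 ± 0.293 CPM, CTXN1 2.5-fold, LMLN 2.37-fold, KRTAP2-3 2.31-fold, SCML1 2.24-fold, NEURL1B 2.19-fold, CPEB3 2.11-fold and FAM81A 2.04-fold. ANGPTL4, an inhibitor of lipoprotein lipase, fell 4.25-fold, CORO2B 3.31-fold, INSIG1 3.26-fold, HMGA1 2.71-fold, SRPX 2.58-fold, MFSD2B 2.5-fold and the surface antigen TACSTD2 2.35-fold. These genes had adjusted p from 9.59e-29 to 3.56e-07 and, by the rule for naming, no overlap between the groups.

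Cholesterol biosynthesis genes were lower under TM with siIGF2BP2, 22 of 25 with 0 higher, and 22 with 1 higher adjusted over the list alone (median -0.33, adjusted p = 5.33e-16, and 0.00214 with an estimated correlation), with INSIG1, MVD (-0.51 ± 0.06), PCSK9 (-0.49 ± 0.06) and LDLR (-0.47 ± 0.05). Glycolysis genes were lower, 17 of 23 with 1 higher (median -0.25, adjusted p = 8.84e-10, and 0.0452 with an estimated correlation), with ALDOC (-0.92 ± 0.09), PFKFB4 (-0.80 ± 0.09), SLC2A1 (-0.58 ± 0.05) and PFKFB3 (-0.46 ± 0.05). PERK-ATF4 targets were lower, 17 of 37 with 3 higher (median -0.091, adjusted p = 0.0121, but 0.353 with an estimated correlation), with DDIT4 (-0.44 ± 0.08), SLC7A5 (-0.38 ± 0.04), VEGFA (-0.38 ± 0.05) and TRIB3 (-0.32 ± 0.05). ATF6 targets were lower, 9 of 18 with 1 higher (median -0.12, adjusted p = 0.000401, but 0.149 with an estimated correlation), with CRELD2 at -0.39 ± 0.05. Immediate early genes were lower, 14 of 29 with 6 higher (median -0.22, adjusted p = 4.87e-05, but 0.149 with an estimated correlation), with KLF2 (-0.78 ± 0.06), FOSL1 (-0.59 ± 0.04) and DUSP6 (-0.47 ± 0.04). Heat shock genes were lower, 14 of 17 (median -0.16, adjusted p = 4.87e-05, but 0.201 with an estimated correlation). Interferon-stimulated genes were higher, 7 of 24 with 2 lower (median 0.25, adjusted p = 0.0159, but 0.149 with an estimated correlation), with OAS3 at 0.57 ± 0.05 and DTX3L at 0.45 ± 0.09. The reported IGF2BP-bound mRNAs had 12 of 31 higher and 7 lower (median 0.072, adjusted p = 0.958, with the test pointing down), again with CDK6 higher (0.70 ± 0.05) and HMGA1 and CCND1 (-0.59 ± 0.03) lower. Single members of other lists that fell were ATP5F1D (-0.92 ± 0.06), SERPINE1 (-0.84 ± 0.06), CCNE1 (-0.73 ± 0.06) and KRT18 (-0.55 ± 0.04). ZFP36L1 rose by 0.56 ± 0.04.

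In TM, siIGF2BP2 called 4443 genes, 2069 higher and 2374 lower, 90 and 27 of them at least 2-fold, and groups did not overlap in 41.7% of genes (10% by chance). Of 2345 lower genes with a searched 3' UTR, 7.8% carried the 7-base sequence GACCATA, against 5.8% of all and 5.2% of higher genes.

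**Figure D3:**
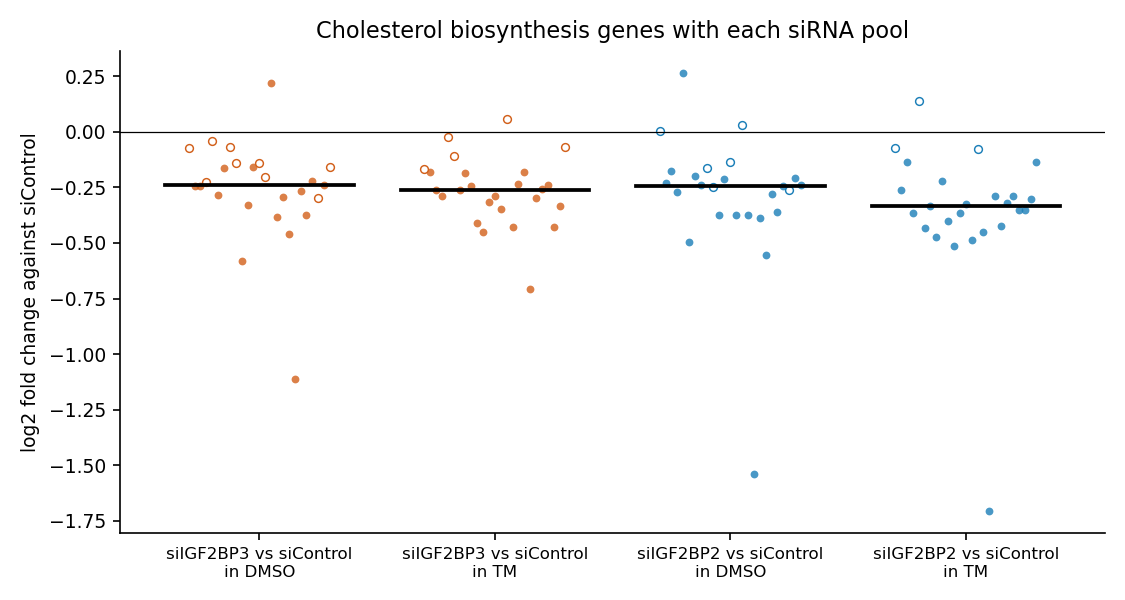
Log2 fold change against siControl of the 25 cholesterol biosynthesis genes with each siRNA pool and treatment (3 libraries per group); filled points passed the gene test, open points did not, and horizontal lines are medians. The medians lie at -0.24, -0.26, -0.24 and -0.33 from left to right.

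**Figure D4:**
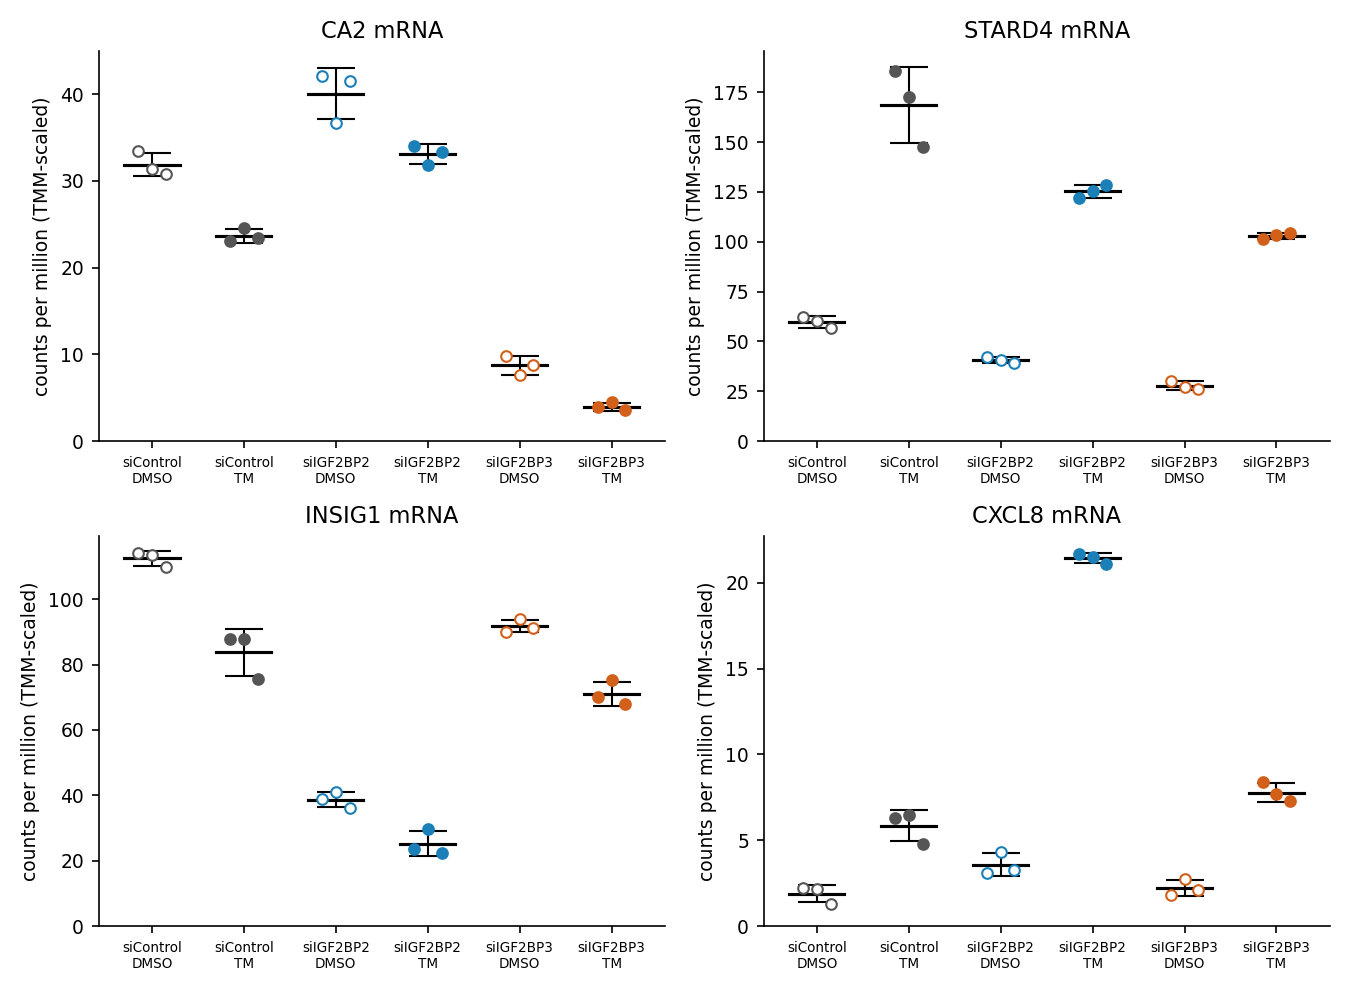
TMM-scaled CPM of CA2, STARD4, INSIG1 and CXCL8 in each library, with the mean (horizontal line) and SD (whiskers) of the 3 libraries per group; open circles are DMSO, filled circles TM. CA2 reaches 3.99 in siIGF2BP3 TM, INSIG1 25.3 and CXCL8 21.4 in siIGF2BP2 TM.

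The difference between both siRNA effects was tested directly, siIGF2BP3 against siIGF2BP2. In DMSO, TNS4 (2.67-fold), CORO2B (2.57-fold), INSIG1 (2.37-fold) and HMGA1 (2.35-fold) were higher with siIGF2BP3, and CA2 (4.59-fold), FBXL2 (2.44-fold), FAM81A (2.28-fold) and ZNF385A (2.21-fold) were lower, beside both targets. In TM the same contrast had ANGPTL4 (1.86 ± 0.20), TNS4 (1.49 ± 0.10), HMGA1 (1.48 ± 0.04) and INSIG1 (1.47 ± 0.07) higher, and CA2 (-3.06 ± 0.09), FBXL2 (-1.73 ± 0.14), ZNF385A (-1.57 ± 0.05) and CXCL8 (-1.47 ± 0.11) lower. The mitotic phosphatase gene CDC25B and the cyclin gene CCND1 were higher with siIGF2BP3 than with siIGF2BP2 in DMSO (0.73 ± 0.04 and 0.52 ± 0.03) and in TM (0.91 ± 0.04 and 0.70 ± 0.03), and CDK6 was lower (-0.69 ± 0.05 and -0.85 ± 0.05). STARD4 was lower with siIGF2BP3 in both (-0.56 ± 0.07 and -0.28 ± 0.06).

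Among the lists, 6 passed in DMSO and 4 in TM, and none did with an estimated correlation. In DMSO, ATF6 targets (11 of 18 higher, median 0.18), heat shock genes (12 of 17 higher, 0.14), PERK-ATF4 targets (17 higher and 4 lower of 37, 0.096) and immediate early genes (13 higher and 5 lower of 29, 0.17) were higher with siIGF2BP3 than with siIGF2BP2. Ribosomal protein genes (36 of 79 lower, -0.11) and OXPHOS genes (4 higher and 20 lower of 66, -0.086) were lower. With an estimated correlation these had adjusted p = 0.105, 0.318, 0.558, 0.465, 0.558 and 0.568. With the GC and length trend removed, the OXPHOS list stood at -0.001 and did not pass (adjusted p = 0.511, range over the alternatives 0.00401 to 0.568). In TM, PERK-ATF4 targets (17 higher and 2 lower, median 0.12), heat shock genes (8 of 17 higher, 0.088), immediate early genes (14 higher and 5 lower, 0.24) and glycolysis genes (13 higher and 2 lower, 0.15) were higher, with adjusted p = 0.673, 0.673, 0.519 and 0.673 with an estimated correlation. Cholesterol biosynthesis genes did not differ past the threshold, with medians of 0.017 in DMSO (adjusted p = 0.488) and 0.050 in TM (adjusted p = 0.189). In all, 3478 genes differed in DMSO (1784 higher and 1694 lower with siIGF2BP3) and 3849 in TM (2039 and 1810), and groups did not overlap in 42.4% and 45.8% of genes (10% by chance). Higher genes made up 51.3% of the DMSO calls, and 62.2% with the GC and length trend removed.

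Both siRNA effects shared a direction in more genes than independent calls would. In DMSO, 211 genes were higher with both pools (61.6 by chance overlap of the calls) and 176 lower (59.2), while 79 went opposite ways. In TM, 394 were higher (119.8), 440 lower (161.6) and 112 opposite. Across genes, which are not independent replicates, the effects correlated at 0.403 in DMSO and 0.448 in TM. Both comparisons use the same siControl libraries, and unchanged groups simulated against them gave a higher mean correlation, 0.533 and 0.52. The covariance of the real effects was larger than the mean of 20 simulations, 0.0211 against 0.0119 in DMSO and 0.0275 against 0.0108 in TM. Each gene was simulated on its own, with a spread pooled over all groups. The GC and length deviation of siControl TM replicate 3, which enters both effects in TM, was thus left out. The larger covariance in TM cannot be told apart from that deviation. The overlap that shared siControl libraries give to calls of groups that do change was not simulated. The siIGF2BP2 pool also lowered IGF2BP3, to 77.2% of control in DMSO, and the part of this in the shared direction was not tested.

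Each siRNA effect was also compared between treatments. With siIGF2BP2, 1096 genes were higher in both DMSO and TM (271 by chance) and 1334 lower (326.7), while 3 went opposite ways, and the effects correlated across genes at 0.656. With siIGF2BP3, 224 genes were higher in both (27.2 by chance), 243 lower (29.3) and 0 opposite, at a correlation of 0.324. Among genes of at least 5 CPM the correlations were 0.819 and 0.609.

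Whether depletion changed the response to ER stress was asked first of the response as a whole. TM called 6065 genes in siIGF2BP2 (3085 higher and 2980 lower) and 6108 in siIGF2BP3 (3174 and 2934), with no overlap of the groups in 57.3% and 56.5% of genes (10% by chance). Of the genes called in siControl, 2475 were also higher and 2247 also lower in siIGF2BP2, with 2 opposite, and 2494 and 2230 in siIGF2BP3, with 4 opposite. DDIT3 rose 82.5-fold in siIGF2BP2 and 62.2-fold in siIGF2BP3, CHAC1 40.8- and 32.4-fold, HERPUD1 26.7- and 22.7-fold, LURAP1L 21- and 20.7-fold and SESN2 16.3- and 16.8-fold. AXIN2 fell 4.24- and 6.68-fold, HSPA1B 5- and 5.16-fold, HSPA1A 4.47- and 5.02-fold and RTN4RL1 3.95- and 3.13-fold. ANGPTL4 fell 3.59- and 1.54-fold, and HOXA13 fell 3.36-fold in siIGF2BP3 and by 1.78 on the log2 scale in siIGF2BP2.

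The stress lists also rose in both siRNA groups. The interaction tests below give the differences from siControl. PERK-ATF4 targets had 36 and 37 of 37 higher (medians 1.19 and 1.23), ATF6 targets 17 of 18 in each (1.74 and 1.53) and IRE1-XBP1 targets 25 and 27 of 32 (0.35 and 0.36). HSPA5 rose by 3.06 ± 0.04 and 2.81 ± 0.04. With an estimated correlation 6 of the 11 lists that passed in siIGF2BP2 and 7 of the 10 in siIGF2BP3 still did. The heat shock list passed in siIGF2BP3 (median -0.37, adjusted p = 0.0263 with an estimated correlation) and was lost in siIGF2BP2 (-0.33, adjusted p = 0.0547 with an estimated correlation).

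Over the 6067 genes called in siControl, the orthogonal slope of the TM response was 0.942 in siIGF2BP2 (0.925 to 0.96 with 1 library left out, r = 0.944 across genes) and 0.925 in siIGF2BP3 (0.901 to 0.934, r = 0.948). Selecting genes by their siControl response pulls a slope under 1, and over genes called in the siRNA group instead the slopes were 1.04 and 1.03.

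**Figure D5:**
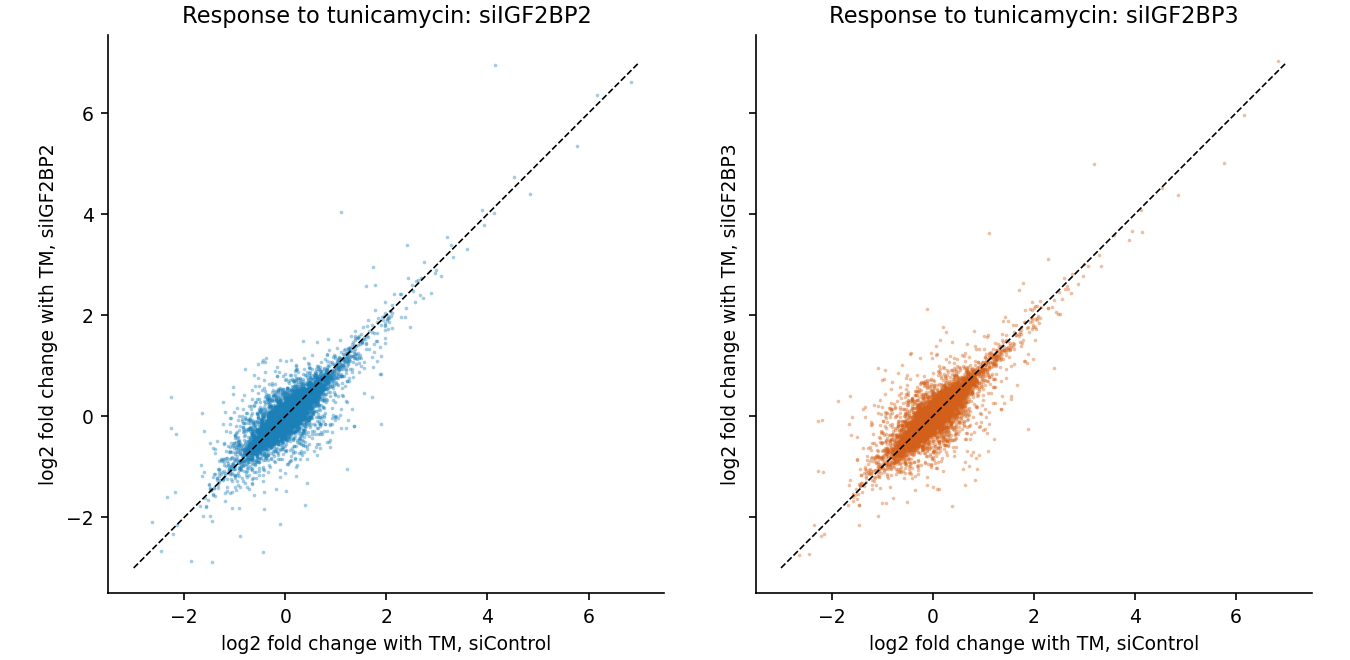
Log2 fold change with TM in siIGF2BP2 (left) and siIGF2BP3 (right) against that in siControl, 1 point per tested gene (12484 genes); the dashed line marks equal responses. Over genes called in siControl the orthogonal slopes are 0.942 and 0.925.

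The interaction of siRNA and treatment tested each gene's response itself. A response here is the log2 fold change with TM, with its sign. For a gene that fell with TM, a lower response is thus a deeper fall, and a higher one a smaller fall or a rise. With siIGF2BP3, 3 genes passed. The response of ZFP36L1 (ENSG00000185650, chromosome 14) was higher by 0.31 ± 0.05 (adjusted p = 0.00348), with 249 and 261 CPM in siControl DMSO and TM against 306 and 397 in siIGF2BP3. The response of SKP2, a ubiquitin ligase subunit that targets cell cycle inhibitors, was higher by 0.37 ± 0.07 (adjusted p = 0.0227), with 86.4 and 52.6 CPM in siControl against 88 and 69.5. The response of CA2 was lower by 0.71 on the log2 scale (adjusted p = 0.0227). SKP2 did not pass without siControl DMSO replicate 1, 2 or 3 (adjusted p = 0.0932, 0.0623 and 0.0623), siControl TM replicate 2 (0.0556), siIGF2BP3 DMSO replicate 1 or 2 (0.102 and 0.14) or siIGF2BP3 TM replicate 1 (0.0787). CA2 did not pass without siControl DMSO replicate 2 or 3 (adjusted p = 0.0623 each), siControl TM replicate 2 (0.0587), siIGF2BP3 DMSO replicate 1 (0.198) or siIGF2BP3 TM replicate 1 or 3 (0.0685 and 0.273). Over the alternatives their adjusted p ran from 0.000827 to 0.14 and from 0.000875 to 0.273. At an unadjusted p under 0.05, 1220 genes passed, and DESeq2 called 21. The count was 1 without siControl DMSO replicate 2 or 3, siControl TM replicate 2, siIGF2BP3 DMSO replicate 1 or siIGF2BP3 TM replicate 1, and 63, 8 and 11 without siControl TM replicate 1, siControl TM replicate 3 and siIGF2BP3 DMSO replicate 3.

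With siIGF2BP2, 44 genes passed in the interaction, 13 higher and 31 lower. SKP2 again had a higher response (0.47 ± 0.07, adjusted p = 0.000184), as did RCAN1, a calcineurin inhibitor (0.56 ± 0.08, adjusted p = 0.000184), and ZFP36L1 (0.27 ± 0.05). ANGPTL4 (-1.42 ± 0.27, adjusted p = 0.00318), the cytokine signalling inhibitor SOCS3 (-0.57 ± 0.11) and KRTAP2-4 (-0.56 ± 0.11) had a lower response. Among list members, HSPA5 (0.31 ± 0.06) and MANF (0.33 ± 0.06) had a higher response, and STC2 (-0.45 ± 0.06), HMGA1 (-0.32 ± 0.05), CCN1 (-0.53 ± 0.09) and DUSP5 (-0.33 ± 0.06) a lower one. At an unadjusted p under 0.05, 1277 genes passed, and DESeq2 called 73. The count was 26 without siControl DMSO replicate 3, 165 without siControl TM replicate 1, 29 and 27 without siIGF2BP2 DMSO replicates 2 and 3, and 28 without siIGF2BP2 TM replicate 1.

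As lists, 8 passed in the siIGF2BP2 interaction and 3 in the siIGF2BP3 interaction, and none did with an estimated correlation. With siIGF2BP2 the response of PERK-ATF4 targets was lower (median -0.10, 2 of 37 members called), of glycolysis genes lower (-0.12, 0 of 23 called), of ATF6 targets higher (0.090, 2 of 18 called) and of G2-M genes higher (0.074, 0 of 30 called), at adjusted p = 0.0746, 0.0746, 0.0793 and 0.0746 with an estimated correlation. Immediate early genes (-0.12, with 3 of 29 called lower and 1 higher), p53 targets (-0.087, 1 of 24 called), cholesterol biosynthesis genes (-0.094, 0 called) and ribosomal protein genes (-0.053, 0 called) had a lower response, at adjusted p = 0.111, 0.107, 0.384 and 0.799 with an estimated correlation. With siIGF2BP3 the response of PERK-ATF4 targets (-0.086) and glycolysis genes (-0.070) was lower and of mitochondrially encoded mRNAs higher (0.061), with 0 members called in each, at adjusted p = 0.271, 0.557 and 0.496 with an estimated correlation. With the GC and length trend removed, the mitochondrially encoded list had a median of -0.004 and did not pass (adjusted p = 0.171, range 2.23e-07 to 0.496), nor did glycolysis (-0.034, 0.175). Without siControl TM replicate 3 the glycolysis list (siIGF2BP3, adjusted p = 0.0919, range over the alternatives 0.0205 to 0.557) and the ribosomal list (siIGF2BP2, adjusted p = 0.872, range 1.12e-05 to 0.872) did not pass.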

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

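The tests of other splits, seed matches, bound mRNAs, cholesterol genes and siControl TM replicate 3 in this part were chosen after the results were seen; the interaction tests were planned.

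The results of this paragraph and the next stand out because the TM response differed between siRNA pools by a test of the difference itself. A higher or lower response refers to the signed log2 fold change with TM. With siIGF2BP3, 3 genes passed, ZFP36L1 (0.308) and SKP2 (0.371) with a higher response and CA2 (-0.711) with a lower one. SKP2 and CA2 fell with TM in siControl and in siIGF2BP3, SKP2 less and CA2 more with siIGF2BP3. SKP2 and CA2 did not pass with the groups compared alone (adjusted p = 0.11 and 0.0922) or without single libraries. With siIGF2BP2, 44 genes passed. Of those named, RCAN1 (0.556), SKP2 (0.466), ANGPTL4 (-1.424), SOCS3 (-0.566) and KRTAP2-4 (-0.563) passed under each alternative run. ZFP36L1 and SKP2 had a higher response with both pools, which share the siControl libraries. CXCL8 (0.987), MTM1 (0.57), TRIQK (0.509), SLC6A9 (-0.705) and ADM (-0.651) passed with all libraries but not under some alternatives. The lists were PERK-ATF4 targets (-0.086), mitochondrially encoded mRNAs (0.061) and glycolysis (-0.07) with siIGF2BP3. With siIGF2BP2 they were PERK-ATF4 targets (-0.103), ATF6 targets (0.09), cholesterol biosynthesis (-0.094), G2-M genes (0.074), p53 targets (-0.087), ribosomal proteins (-0.053), immediate early genes (-0.123) and glycolysis (-0.116). None of the 11 passed camera with an estimated correlation, while the preset correlation passed all 11, and fry passed 0 lists with siIGF2BP3 and 6 with siIGF2BP2.

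Among the named genes above, these calls depend on single libraries. With siIGF2BP3, SKP2 did not pass without siControl DMSO replicate 1, 2 or 3 (adjusted p = 0.0932, 0.0623 and 0.0623), siControl TM replicate 2 (0.0556), siIGF2BP3 DMSO replicate 1 or 2 (0.102 and 0.14) or siIGF2BP3 TM replicate 1 (0.0787), in a range of 0.000827 to 0.14. CA2 did not pass without siControl DMSO replicate 2 or 3 (0.0623 each), siControl TM replicate 2 (0.0587), siIGF2BP3 DMSO replicate 1 (0.198) or siIGF2BP3 TM replicate 1 or 3 (0.0685 and 0.273), in a range of 0.000875 to 0.273. With siIGF2BP2, CXCL8 did not pass without siControl DMSO replicate 1 or 2 (adjusted p = 0.241 and 0.204), siControl TM replicate 3 (0.0977), siIGF2BP2 DMSO replicate 1 or 3 (0.129 and 0.111) or siIGF2BP2 TM replicate 1, 2 or 3 (0.0872, 0.0712 and 0.0662), in a range of 0.00368 to 0.241. MTM1 did not pass without siControl DMSO replicate 2 or 3 (0.102 and 0.107), siControl TM replicate 3 (0.108), siIGF2BP2 DMSO replicate 2 or 3 (0.0863 and 0.0617) or siIGF2BP2 TM replicate 1 (0.111), in a range of 0.0111 to 0.111. TRIQK did not pass without siControl DMSO replicate 3 (0.0794), siControl TM replicate 3 (0.0805), siIGF2BP2 DMSO replicate 2 or 3 (0.0624 and 0.0571) or siIGF2BP2 TM replicate 3 (0.0682), in a range of 0.0011 to 0.0805. SLC6A9 did not pass without siControl DMSO replicate 1, 2 or 3 (0.192, 0.0989 and 0.107), siControl TM replicate 3 (0.0929), siIGF2BP2 DMSO replicate 1, 2 or 3 (0.0881, 0.0556 and 0.199) or siIGF2BP2 TM replicate 1, 2 or 3 (0.0646, 0.0835 and 0.105), in a range of 0.0114 to 0.199. ADM did not pass without siControl DMSO replicate 1 (0.0671), siIGF2BP2 DMSO replicate 2 (0.0863) or siIGF2BP2 TM replicate 1 (0.0523), in a range of 2.01e-07 to 0.0863. Of list members not named above, PPP1R15A, EGR1 and SYVN1 also passed with all libraries and not without some. PPP1R15A did not pass without siControl DMSO replicate 1 or 3 (0.0671 and 0.0794) or siIGF2BP2 DMSO replicate 3 (0.0626), in a range of 4.74e-06 to 0.0794. EGR1 did not pass without siControl DMSO replicate 3 (0.0608), siIGF2BP2 DMSO replicate 2 (0.0624) or siIGF2BP2 TM replicate 1 (0.0663), in a range of 6.82e-05 to 0.0663. SYVN1 did not pass without siIGF2BP2 DMSO replicate 2 (0.0863), in a range of 8.03e-05 to 0.0863.

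Other splits of the libraries bear on these counts. The siRNA labels were exchanged within each treatment, with the additive effects of siRNA and treatment held fixed per gene. For the siIGF2BP3 interaction, 1 of 100 splits, the real one, called at least 3 genes, and the highest other called 1. For the siIGF2BP2 interaction, 1 of 100, the real one, called at least 44, and the highest other called 15. No other split drawn reached either count. The additive effects were fitted with the real labels, so these splits do not exclude chance. The count with siIGF2BP3 rests on 3 genes. It falls to 1 without siControl DMSO replicate 2 or 3, siControl TM replicate 2, siIGF2BP3 DMSO replicate 1 or siIGF2BP3 TM replicate 1. The effects were held fixed only after a first run of the same splits had been seen. In that run, where the siRNA effect itself can pass into the interaction, 13 and 10 of 100 splits called as many genes, with 730 and 2547 as the highest others, so it does not speak to chance. For the 9 comparisons of 3 against 3 libraries, 1 of 10 splits, the real one, called as many genes, and the highest other called 0 by edgeR, but 10 splits are too few for a share under 0.05.

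With each siRNA pool, genes with one 7-base sequence were on average lower, as seed matches of an siRNA would make them. Genes with TCAGGTA in the 3' UTR (1163 of 12296 searched) were lower with siIGF2BP3, and those with GACCATA (718) with siIGF2BP2; each was found in DMSO (z = -6.11 and -5.79) and ranked 1 of 16240 in TM, at z = -8.14 and -7.46 against a Bonferroni limit of 4.67. With the other pool z was 0.51 and 1.65, and the target transcript of each pool holds its sequence (4 copies and 1). Seed matches of the siRNAs may therefore account for part of the lower genes. For these sequences alone the part was small on average (-0.05 ± 0.01 and -0.08 ± 0.01 in TM). The first was carried by 13.2% of lower, 10.5% of higher and 9.5% of all genes, and the second by 7.8%, 5.2% and 5.8%. In TM, ATCAGTT (z = -6.49), ACCCGGA (-5.74), CCCGGAA (-5.55) and GGACGTT (-5.18) with siIGF2BP2 were past the limit among lower genes too. So was TTCAGGT (-5.16) with siIGF2BP3. The share of all seed matches of a pool was thus not measured. CAGGTAA with siIGF2BP3, and the AU-rich TTTTTAA (6426 genes) and TTTTTTA (5820) with siIGF2BP2, also passed the limit in DMSO. So did sequences among higher genes, ACCGGCG with siIGF2BP2 in DMSO (z = 4.77) and TGACTAA (5.13) and AGACTAA (4.71) with siIGF2BP3 in TM. Seed matches of the target pools do not explain these. The siControl pool is in each of these comparisons, and seed matches of its siRNAs were not tested. Loss of IGF2BP3 from mRNAs reported to be bound stays open, because the list median of -0.002 lies over members that go both ways (SD 0.216), and the siRNA sequences are not given.

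Cholesterol biosynthesis genes were lower with both pools in both treatments. A GC and length trend as the whole cause is argued against by list medians that stayed at -0.238 or lower with the trend removed. Matches to the leading sequence of each pool in the members' own 3' UTRs are argued against as the whole cause. The 23 of 25 members without it had a weakest median of -0.238. A match in another gene that acts on these members was not tested and stays open. Matches to other siRNAs of the pools stay open, because their sequences are not given; members without any sequence past the limit in DMSO (23 with siIGF2BP3 and 11 with siIGF2BP2) had a weakest median of -0.21. An effect of the control pool that raises these genes cannot be told apart from an effect of both target pools. The list median of siIGF2BP3 against siIGF2BP2 was 0.017 in DMSO, and no untransfected cells were sequenced. Single members did differ there, INSIG1 by 1.245, and STARD4 (-0.556), HSD17B7 (-0.329) and PMVK (-0.308) the other way. The control pool, which is not in that comparison, does not account for these differences. A shared action of IGF2BP2 and IGF2BP3 on sterol synthesis stays open and untested. Whether the fall of IGF2BP3 with siIGF2BP2 in DMSO had a part was not tested either.

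In siControl TM, replicate 3 stood apart from replicates 1 and 2. A GC and length trend explained 57.4% of its deviation, against at most 24.1% in libraries of other groups. Distance was measured as chi-square per degree of freedom between 2 libraries. Removing the trend lowered the mean distance of replicate 3 to replicates 1 and 2 from 9.49 to 3.73. The highest single pair in other groups then stood at 2.92. Such a trend may thus be the main part of the deviation, though not all of it. A sample with a wrong treatment label is argued against by 98.1% of 260 TM-responsive genes on the TM side of the siControl DMSO libraries, and a wrong siRNA label by IGF2BP2 and IGF2BP3 at 96.8% and 86.3% of the other replicates. No biological explanation was tested.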

How the results depend on the processing

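Removal of the GC and length trend and list tests without siControl TM replicate 3 were tests chosen after the results were seen; the other alternatives were planned.

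Among named genes, direction and side of the threshold were the same for all 352 values under RLE scaling, for 350 of 352 without the filter while with 1 library left out 2214 were the same, 66 no longer passed and 6 newly passed. With the groups alone 6 calls were lost (SDF2L1 with siIGF2BP3 in TM, and SKP2, CA2, CXCL8, MTM1 and SLC6A9 in interactions). With the GC and length trend removed 2 were lost, 4 gained and 1 reversed, by DESeq2 1 was lost and 2 gained, and with the stricter filter 1 was gained. Both knockdowns kept log2 fold changes of -2.14 to -2.08 (IGF2BP3, DMSO), -2.43 to -2.31 (TM), -2.49 to -2.38 (IGF2BP2, DMSO) and -2.77 to -2.63 (TM) with 1 library left out. Causes of the changes given here were not tested unless the alternative itself shows one.

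Counts of called genes moved in few comparisons. The siIGF2BP3 interaction called 41 genes without the filter, 21 by DESeq2, 10 with the GC and length trend removed, 1 with the groups alone and 5 with a replicate block. The siIGF2BP2 interaction called 92 without the filter, 73 by DESeq2 and 79 with the trend removed. With a replicate block, the response of IGF2BP3 in that interaction, 0.28, passed at adjusted p = 0.0352 (range 0.00321 to 0.157), and that of IGF2BP2, -0.282, at 0.0431 (range 0.0197 to 0.466). With the groups alone, a fit with fewer libraries, siIGF2BP3 called 1387 in DMSO and 675 in TM.

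With 1 library left out, siIGF2BP3 called 486 to 867 in DMSO (589, 532 and 593 without siControl DMSO replicates 1, 2 and 3, and 548 and 486 without siIGF2BP3 DMSO replicates 1 and 2). In TM it called 1005 to 2040, the lowest without siIGF2BP3 TM replicate 3. The siIGF2BP3 interaction called 1 to 63, with 1 without siControl DMSO replicate 2 or 3, siControl TM replicate 2, siIGF2BP3 DMSO replicate 1 or siIGF2BP3 TM replicate 1, and 63, 8 and 11 without siControl TM replicate 1, siControl TM replicate 3 and siIGF2BP3 DMSO replicate 3. The siIGF2BP2 interaction called 26 to 165, with 26 without siControl DMSO replicate 3, 165 without siControl TM replicate 1, 29 and 27 without siIGF2BP2 DMSO replicates 2 and 3 and 28 without siIGF2BP2 TM replicate 1.

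Counts of lists that passed differed between list tests. With an estimated correlation, 7 lists passed for TM in siControl and 6 in siIGF2BP2, 1 for siIGF2BP3 in DMSO and 1 in TM, 2 for siIGF2BP2 in DMSO and 2 in TM, and 0 for each direct contrast (6 and 4 with the preset one) and each interaction (3 and 8). With fry, which compares a list with no other genes, 19, 20 and 19 passed for TM in siControl, siIGF2BP2 and siIGF2BP3, 10 for siIGF2BP3 in TM, 13 and 15 for siIGF2BP2 in DMSO and TM, 15 and 12 for the direct contrasts and 0 for the siIGF2BP3 interaction. For siIGF2BP2 in DMSO, 9 passed under RLE scaling and 9 with the trend removed. For the siIGF2BP3 interaction 6 passed with a replicate block and 5 without siControl TM replicate 3.

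The test changed direction in 2 results. With the GC and length trend removed, IGF2BP3 with TM in siIGF2BP2 stood at -0.096 (adjusted p = 0.0336, in a range of 0.0336 to 0.992) and not at 0.012. Without siControl TM replicate 3, ribosomal protein genes with siIGF2BP3 in TM stood at 0.006 (adjusted p = 0.729, in a range of 0.00106 to 0.729) and not at -0.057. With the trend removed, 5 lists no longer passed. Mitochondrially encoded mRNAs in the siIGF2BP3 interaction went from a median of 0.061 to -0.004 (adjusted p = 0.171, in a range of 2.23e-07 to 0.496), a change of sign of the median, and glycolysis there from -0.07 to -0.034 (0.175, range 0.0205 to 0.557). OXPHOS genes in siIGF2BP3 against siIGF2BP2 in DMSO went from -0.086 to -0.001 (0.511, range 0.00401 to 0.568), ribosomal protein genes with siIGF2BP3 in TM to -0.039 (0.0586) and IRE1-XBP1 targets with siIGF2BP3 in DMSO to -0.049 (0.0624, range 0.0143 to 0.524).

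Among genes of at least 5 CPM, both siRNA effects correlated at 0.325 in DMSO and 0.383 in TM, under the 0.525 and 0.517 that unchanged groups simulated against the same siControl libraries gave. For these genes the TM slopes were 0.973 and 0.97 (siIGF2BP2 and siIGF2BP3), and the DMSO and TM effects correlated at 0.819 and 0.609. Over genes called in the siRNA group the slopes were 1.043 and 1.03. With 1 library left out, the siRNA effects correlated at 0.374 to 0.528 and 0.406 to 0.525, the slopes were 0.925 to 0.96 and 0.901 to 0.934, and the DMSO and TM effects correlated at 0.589 to 0.629 and 0.253 to 0.3. Depth was not varied, so its share in what limits the calls was not tested; 78% of simulated 1.5-fold changes were recovered in the siIGF2BP3 interaction and 94% in siIGF2BP3 against siControl in DMSO.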

Other observations

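The test of mitochondrially encoded mRNAs and the scan of gene families in this part were chosen after the results were seen. The Wnt list was written before its values were, but the condition on its spread was added after.

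AXIN2 was among the genes with the largest fall under TM. Lower expression of Wnt target genes in general was tested as a hypothesis on the 12 other tested members of a list of 16. Their median in siControl was -0.087 with an SE of 0.226, a spread too wide to tell. The list did not pass limma's camera. Of its members 3 were higher and 5 lower. The labelling rule first read this value as excluding the hypothesis, and the spread condition was added once the value had been seen.

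MT-ND6, the mitochondrial mRNA encoded on the light strand, was higher with siIGF2BP2 by 0.64 ± 0.08 in DMSO and 0.78 ± 0.08 in TM. It was also higher with siIGF2BP3 in TM (0.35 ± 0.08, adjusted p = 0.00236), though not past the threshold without siIGF2BP3 TM replicate 2 (0.0586, in a range of 4.11e-16 to 0.0586 over the alternatives). Its counts depend on the strand setting, which is not given. More mitochondrial RNA of all kinds is argued against, since MT-CO1 (-0.257 in DMSO and -0.263 in TM) and MT-ND5 (-0.137 and -0.165) fell. The other 12 mitochondrially encoded mRNAs went both ways, 3 higher and 3 lower in each treatment, with a median of -0.052 in DMSO and 0.014 in TM. MT-ND2 (0.293 and 0.367) and MT-ND3 (0.251 and 0.331) rose with MT-ND6, so a rise of part of these mRNAs is not argued against.

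A scan of 117 gene families of at least 12 members, named by the stem of their symbols, passed some with camera at the preset correlation. With TM in siControl, 16 of 26 HOX genes were lower and 2 higher (median -0.486, adjusted p = 0.208 with an estimated correlation), and 13 of 25 SEC genes were higher and 1 lower (0.168, 0.107). With TM in both target pools SEC genes also passed at the preset correlation, and HOX genes did not. With siIGF2BP2 in DMSO, 72 of 360 ZNF genes were higher and 6 lower (0.12, 0.26), 6 of 15 IFT genes were higher (0.239, 0.26) and 6 of 16 keratin genes were lower (-0.261, 0.289). The stem that also passed with an estimated correlation was ZFP with siIGF2BP3 in TM, with 3 of 14 genes higher and 0 lower (0.115, 0.0478). Its higher genes include ZFP36L1 (0.605) and ZFP36L2 (0.367), described above among the mRNA decay factors. A shared stem need not mark related genes, and the adjustment covered the families of 1 comparison at a time. The scan was run neither with the GC and length trend removed nor without siControl TM replicate 3.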
